A study of Danio rerio with 8 samples.

How the data were processed

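Bulk RNA sequencing was carried out on tail muscle that still held its intermuscular bones, taken from zebrafish at 60 days post fertilization. Per the labels' protocols, the tissue was frozen on dry ice, RNA was extracted with Trizol, and libraries were built with a stranded kit for polyadenylated RNA (TruSeq Stranded mRNA). The labels place 3 bulk libraries in the wild type group and 3 in the runx2b-/- group, all in a line that carries an sp7:eGFP transgene. The series also has 2 single-cell samples, 1 per genotype, which were not analysed here.

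The deposited table held whole-number read counts per gene for the 6 bulk libraries, without normalization and without pooling of replicates. Its columns, per the file headers, are gene symbol, chromosome, start, end, strand, length and the 6 counts. The aligner, the counting program, the treatment of reads that fit several genes and the strand setting of the count were not given in the sources used here. The submitters' processing notes name Cell Ranger and the build GRCz11, without tying either to this table, and the table itself names no build. Positions are therefore printed as the table gives them. Of 25279 gene symbols, 114 had parts on more than 1 chromosome and were given no position. Reads of near-identical paralogs, of overlapping genes and of antisense partners could have been split or merged by such a count. Of the 62 called genes named in the report, 27 have a model that overlaps the model of another tested gene and 12 overlap another called gene; values of these 12 and of near-identical paralogs are uncertain.

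Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and with DESeq2 1.42.0 as an alternative. Genes were kept by edgeR's filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which left 14107 genes. Library sizes were scaled with trimmed mean of M-values (TMM) factors of 0.882 to 1.13. The genotypes were compared with edgeR's quasi-likelihood test (robust glmQLFit and glmQLFTest, no covariate), and p-values were adjusted with the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.05, with no fold threshold. Log2 fold changes are mutant minus wild type, and their standard error (SE) is the absolute log2 fold change divided by the square root of the quasi-likelihood F. CPM values use the TMM-scaled library sizes. Ratios of low counts have 95% exact binomial (Clopper-Pearson) intervals. Where a group had 0 counts, a bound was computed against 3 counts over that group, which leaves out the counting error of the other group. Such intervals and bounds cover counting error only.

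A set of 32 gene lists for bone, tendon, cartilage, muscle, signalling, metabolism, stress, clock, immune and other cell types was fixed before the data were examined, as were the tests and the rule for naming genes. The rule took runx2b, runx2a and a list of genes tied to intermuscular bone. It then took the 10 called genes with the largest rise and the 10 with the largest fall, among genes whose groups did not overlap, whose higher group had a mean of at least 1 CPM and whose symbol was not a clone or automatic name. From each list it took up to 4 called members with the smallest adjusted p, or up to 2 abundant members where none was called. Clone names were passed over for 10 rising and 12 falling genes. Each list was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 32 lists. Calls on single chromosomes were tested with Fisher's exact test, two-sided.

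The test was checked on simulated counts for this comparison, drawn with the mean CPM, the dispersion of each gene and the library sizes of the real data. In a run on 13786 genes, 50 genes were planted at each fold size. edgeR recovered 2% of 1.5-fold, 26% of 2-fold, 88% of 4-fold and 88% of 8-fold changes, each with the planted direction. Beside the 102 planted genes that it recovered out of 200, edgeR made 12 false calls. The false share of its calls in that run was therefore above the threshold set for the adjusted p. How far this holds for the called genes of the real data was not tested. A list planted at 2-fold in a run on 13701 genes had a camera adjusted p of 1.43e-19, or an adjusted p of 0.0178 with an estimated correlation, and none of the 31 other lists was called either way. The simulated genes were drawn independently, whereas the estimated correlation in the real lists reached 0.42 (cell cycle). This run therefore cannot show how often camera calls lists of correlated genes falsely.

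Total counts ran from 17280098 to 20482003 per library, and 3 counts corresponded to 0.134 to 0.181 CPM. Libraries of a group differed by more than sampling noise, with chi-square over its degrees of freedom between 25.6 and 95.7, so each was kept as 1 replicate. The alternatives were other scalings, no filter and a stricter filter, DESeq2, limma voom, a replicate block, a fold threshold, a stricter adjusted p and the removal of each library in turn. A correction for gene length, removal of mitochondrially encoded and abundant genes, and removal of both wild type libraries with egg coat transcripts were added after the data had been seen. The last of these leaves a lone wild type library, assumed to vary like the mutant libraries. Its p-values and calls therefore do not measure the spread within wild type.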

Results

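Intermuscular bones are thin bones that form within the myosepta, the connective tissue sheets between the muscle segments of teleost fish. The series set runx2b-/- zebrafish beside wild type fish to find genes that go with the formation of these bones. runx2b encodes 1 of the zebrafish Runx2 proteins, transcription factors that drive osteoblast differentiation. Bulk RNA was counted in 3 wild type and 3 mutant libraries of tail muscle with its bones, at 60 days post fertilization. Total counts were 19910269, 20482003 and 19890668 in wild type libraries 1 to 3, and 19152567, 17280098 and 20429162 in mutant libraries 1 to 3. Muscle transcripts dominated: the fast myosin heavy chain gene myhc4 alone held a mean of 17.3% of counts, and the 10 most abundant genes of each library held 47.4% to 54.8%. The labels do not say whether libraries of a group came from separate fish, so p-values measure only the spread between these samples, which may be technical.

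The mutated gene was barely detected. runx2b (chromosome 20, 44097770 to 44193546) had 2, 2 and 6 counts in the wild type libraries and 4, 2 and 6 in the mutant libraries. The ratio of mutant to wild type was 1.304, with a 95% counting interval of 0.516 to 3.37, and the gene was too low to pass the count filter of edgeR. A mutation need not lower its transcript, so these counts do not check the genotype labels. Its paralog runx2a had 6 counts in wild type and 5 in mutant. sp7, an osteoblast transcription factor, had 7 counts in wild type and 0 in mutant, which is at least 2.15-fold lower when set against 3 counts over the mutant group (the 95% counting interval starts at 1.33-fold), and was also too low to pass that filter (DESeq2 unadjusted p = 0.123).

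Mutant tail muscle held less RNA of the osteocalcin-like bone gene bglapl, 2.12 ± 1.16 against 17.9 ± 4.79 CPM (counts scaled by library size; mean ± SD, n = 3 each), which is 8.56-fold lower. Of 18 tested genes of red blood cells 8 rose, among them the anion exchanger gene slc4a1a at 43.5 ± 8.05 against 12.05 ± 1.42 CPM, or 3.61-fold higher. Fewer red blood cell genes were called higher without wild type library 2 or any single mutant library. The egg yolk precursors vtg1, vtg4, vtg5 and vtg7 fell to 4 counts or fewer each over the 3 mutant libraries. The sources used here do not give sex, so for these genes a difference in sex and an effect of the genotype cannot be told apart. For the other called genes a difference in sex was not tested either, and it could add to their calls. The glycolytic enzyme gene gpib fell 33.6-fold, and the neutrophil gene lyz had 85 counts in wild type and 2 in mutant. The muscle attachment genes xirp2a and xirp2b rose 1.94-fold and 2.43-fold. The calls of bglapl, xirp2a and xirp2b were each lost when certain single libraries were left out. Those of slc4a1a, gpib, lyz and the vitellogenin genes were kept without each single library.

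Of 14107 tested genes, 476 were called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 248 were higher and 228 lower in the mutant, and 311 differed by at least 1 on the log2 scale (141 higher, 170 lower). Direction went with gene length: across tested genes the log2 fold change rose with length (Spearman's rho 0.187; genes are not independent replicates), with a median of -0.11 in the shortest and 0.19 in the longest of 10 length classes. The shortest class had 17 higher and 46 lower called genes, the longest 55 higher and 17 lower. With a correction for length 420 genes were called, of which 385 were shared, and 11 of the 62 called genes named here lost their call. An unadjusted p under 0.05 was reached by 2732 genes. The groups did not overlap in any of the 476 called genes, nor in 3468 tested genes (24.6%, where chance gives 10%). On the first principal component (44% of variance) the wild type libraries lay at -43.0, -39.2 and -15.4 and the mutant libraries at 37.7, 25.1 and 34.7. The second component (22.5%) spread the wild type libraries from 35.13 (library 1) to -45.6 (library 3). The number of calls depended on single libraries: it was 146 without wild type library 2, 1225 without wild type library 3, 133 without mutant library 1, 155 without mutant library 2 and 115 without mutant library 3. Among the 62 called genes named here, the 18 that stayed called without each single library in turn were adamts14, bmpr1bb, btr07, ctsba, epcam, gpib, jam3b, lyve1a, lyz, pcolceb, plin2, prok1, slc4a1a, tulp1a, vtg1, vtg4, vtg5 and vtg7. All adjusted p-values of genes in what follows come from this edgeR test with Benjamini-Hochberg adjustment, unless another tool is named.

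**Figure D1:**
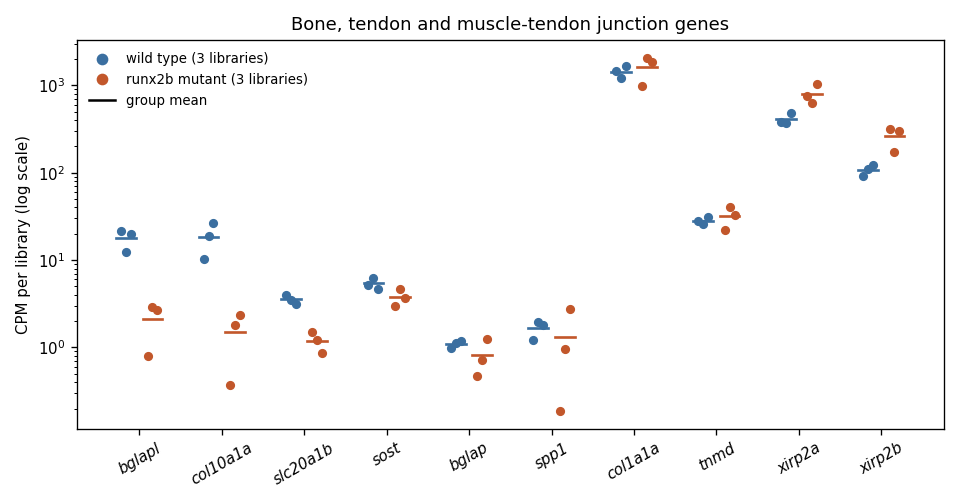
CPM of 10 bone, tendon and muscle attachment genes on a log axis, with 1 point per library (3 wild type, 3 mutant) and a line at each group mean. The mutant libraries lie below the wild type libraries for bglapl, col10a1a and slc20a1b and above them for xirp2a and xirp2b; col10a1a did not pass the test (edgeR adjusted p = 0.0667).

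In the mineralized bone list, 2 of 15 tested members fell and none rose, or 5 lower when adjusted over the list alone. They were bglapl (unplaced scaffold, 8442 to 10291; log2 fold change -3.10, SE 0.45, edgeR adjusted p = 0.0164) and slc20a1b, a sodium-dependent phosphate transporter gene (chromosome 10, 17755611 to 17770731; -1.56, SE 0.26, adjusted p = 0.00834). The list as a whole was lower, with a median log2 fold change of -0.44 and a camera adjusted p of 0.000827; that call was lost with an estimated correlation (adjusted p = 0.332). The collagen X gene col10a1a (chromosome 17, 15534144 to 15538929) stood at 1.51 ± 1.02 CPM in mutant and 18.4 ± 8.13 in wild type, a difference of -3.63 (SE 0.69) with edgeR adjusted p = 0.0667. The same gene had an adjusted p of 0.000317 with DESeq2, 0.0133 with limma voom and 0.0294 with edgeR without mutant library 1, but 0.105 with edgeR without a filter, 0.208 without wild type library 2, 0.182 without mutant library 2 and 0.151 without mutant library 3; over all settings it ran from 0.000197 to 0.208. bglap (-0.44, SE 0.39), entpd5a (-0.52, SE 0.45), sost (-0.51, SE 0.22) and spp1 (-0.36, SE 0.76) differed by less than the test could separate. The call of bglapl ended without wild type library 1 or mutant library 2 or 3 (edgeR adjusted p of 0.0506 to 0.0868), and that of slc20a1b without mutant library 2 or 3 (0.0502 to 0.0595). The list had 3 lower members without mutant library 1 and 0 without mutant library 2 or 3.

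The list of genes tied to intermuscular bone held 18, of which 13 were tested. Of these, 1 was higher (xirp2a) and 1 lower (bglapl), or 1 higher and 2 lower when adjusted over the list alone. The camera adjusted p was 0.287, and it was 0.0493 with library size only and 0.0330 with a replicate block. In the last 2 settings the camera adjusted p with an estimated correlation was 0.879 and 0.906. If such genes were chosen on these samples, the count adjusted over the list alone is not independent evidence. alpl had 19 counts in each group and scxb 16 in wild type and 8 in mutant, and neither passed edgeR's count filter; without the filter edgeR's adjusted p was 0.954 and 0.675, and DESeq2's was at least 0.883 for both. Type I collagen was abundant and not called, with col1a1a at 1636 ± 571 against 1435 ± 224 CPM (log2 fold change 0.19, SE 0.25) and col1a2 at 0.21 (SE 0.21). In the fibrillar collagen list, 3 of 38 tested members rose and 1 fell, or 5 and 3 when adjusted over the list alone (camera adjusted p = 0.852); without wild type library 3 it was 6 and 4. pcolceb, an enhancer of procollagen C-terminal cleavage, fell by 2.45 on the log2 scale (SE 0.31, edgeR adjusted p = 0.0011). The procollagen N-propeptidase gene adamts14 rose by 1.88 (SE 0.27, adjusted p = 0.00278). The collagen hydroxylase genes plod2 (0.79, SE 0.19, adjusted p = 0.0446) and p3h2 (0.88, SE 0.22, adjusted p = 0.0499) also rose. The calls of plod2 (adjusted p up to 0.192) and p3h2 (up to 0.177) ended when wild type library 2 or any 1 mutant library was left out, and that of p3h2 also without wild type library 1. Both also ended with DESeq2 (adjusted p of 0.0578 and 0.110), limma voom (0.0554 and 0.0584), upper-quartile scaling (0.0508 and 0.0515), library size only (0.156 and 0.118) and the replicate block (0.0680 and 0.0841).

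No member of the osteoblast transcription factor, chondrocyte or osteoclast lists was called by edgeR in the main setting. Without a count filter edgeR called 1 osteoblast transcription factor higher and 2 osteoclast genes lower. With library size only it called 1 chondrocyte gene lower. Among 13 tested osteoblast transcription factors, 4 had an unadjusted p under 0.05, DESeq2 called 1 and voom 0, and 1 was higher when adjusted over the list alone (camera adjusted p = 0.852). The abundant members mef2ca and mef2cb stood at 0.63 (SE 0.18, adjusted p = 0.0725) and -0.02 (SE 0.16). Among 13 chondrocyte genes, 5 had an unadjusted p under 0.05, DESeq2 called 1 and voom 1, and none passed when adjusted over the list alone (camera adjusted p = 0.964). The cartilage collagens col11a1b (0.18, SE 0.22) and col2a1b (0.06, SE 0.22) were not called. Among 14 osteoclast genes, 2 had an unadjusted p under 0.05, DESeq2 and voom called 0, and 0 passed when adjusted over the list alone (camera adjusted p = 0.412). The membrane metalloproteinase genes mmp14a (-0.03, SE 0.16) and mmp14b (0.28, SE 0.19) were not called.

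In the tendon and myoseptum list, 2 of 28 tested members rose and none fell, over all genes and when adjusted over the list alone (camera adjusted p = 0.256, which was 0.0242 without mutant library 1, with adjusted p = 0.788 with an estimated correlation). The number of higher members was 4 without wild type library 3 and 0 without wild type library 2 or mutant library 1 or 3. xirp2a and xirp2b encode Xin actin-binding repeat proteins of muscle. xirp2b (1.28, SE 0.22, edgeR adjusted p = 0.0105) and xirp2a (chromosome 6, 9934702 to 9998111; 0.95, SE 0.20, adjusted p = 0.0222) lost their calls without wild type library 2 or mutant library 1 or 3 (adjusted p of 0.0639 to 0.0688 and of 0.0784 to 0.134). Both lie in the longest class of genes (10022 and 13117 bases), and xirp2a lost its call with the length correction (adjusted p = 0.0850). The tendon genes scxa (-0.04, SE 0.22) and tnmd (0.17, SE 0.21) were not called.

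Among 37 fast muscle genes, 1 rose and 3 fell, or 4 and 3 when adjusted over the list alone (camera adjusted p = 0.888). mybpc2b, a fast myosin binding protein gene, rose by 1.70 (SE 0.29, edgeR adjusted p = 0.0155). The myosin heavy chain genes myhz1.3 (-1.85, SE 0.28, adjusted p = 0.00725), myha (-1.75, SE 0.29, adjusted p = 0.0114) and myhz1.2 (-1.27, SE 0.29, adjusted p = 0.0476) fell. These myosins lie side by side on chromosome 5 and are near-identical, so their split of reads is uncertain, and the model of myhz1.3 overlaps on the opposite strand a clone-named gene that was itself lower (-4.94). myhz1.2 lost its call without each single library (adjusted p up to 0.161), myhz1.3 without mutant library 2 (0.0502), myha without wild type library 2 or mutant library 2 (0.0558 to 0.0570) and mybpc2b without wild type library 1 or 2 or mutant library 1 or 3 (up to 0.107). Of 23 slow muscle genes, edgeR called 0, with 6 at an unadjusted p under 0.05, 0 by DESeq2, 1 by voom and 0 when adjusted over the list alone (camera adjusted p = 0.313). The slow muscle list was higher without wild type library 1 (camera adjusted p = 0.0230; adjusted p = 0.809 with an estimated correlation), with 2 members called. Without wild type libraries 1 and 2 the camera direction was up for the slow muscle list and down for the fast muscle list. That setting leaves a lone wild type library, so it holds no spread within wild type. smyhc2 stood at 0.21 (SE 0.17) and tnnt2e at -0.06 (SE 0.19).

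Of 21 tested genes of muscle progenitors and regeneration, 2 rose and 1 fell, or 4 and 2 when adjusted over the list alone (camera adjusted p = 0.880). The rises were in jam3b, an adhesion gene used in myocyte fusion (1.04, SE 0.16, edgeR adjusted p = 0.00551), and cdh15, the gene of M-cadherin (1.41, SE 0.23, adjusted p = 0.0079). The non-muscle myosin gene myh9a fell by 0.70 (SE 0.16, adjusted p = 0.0377). cdh15 lost its call without mutant library 1 or 3 (0.0515 to 0.0588), and myh9a when wild type library 2 or any 1 mutant library was left out (0.123 to 0.172).

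In the BMP and TGF-beta list, 3 of 48 tested members rose and none fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0841, which was 0.0428 without mutant library 3 and 0.0257 with at least 50 counts in 3 libraries; adjusted p = 0.616 and 0.403 with an estimated correlation). They were the receptor genes bmpr1bb (14.7 ± 2.55 against 5.36 ± 1.11 CPM; 1.46, SE 0.20, edgeR adjusted p = 0.00269) and bmpr2b (0.86, SE 0.21, adjusted p = 0.0473) and the ligand gene tgfb2 (0.76, SE 0.18, adjusted p = 0.0416). The calls of bmpr2b (adjusted p up to 0.165) and tgfb2 (up to 0.196) ended when wild type library 2 or any 1 mutant library was left out, and that of bmpr2b also without wild type library 1. Both also ended with limma voom (0.0563 and 0.0613), library size only (0.140 and 0.143) and the replicate block (0.0822 and 0.0710), and bmpr2b with DESeq2 (adjusted p = 0.109) and upper-quartile scaling (0.0508). Without 1 library at a time the log2 fold change ran from 0.838 to 0.889 for bmpr2b and from 0.667 to 0.885 for tgfb2. The ligand genes bmp6 (-0.04, SE 0.45) and mstnb (0.32, SE 0.17) were not called. In the Wnt list, 1 of 31 members was called, over all genes and when adjusted over the list alone (camera adjusted p = 0.857): frzb, a secreted Wnt antagonist, fell by 1.27 (SE 0.26, edgeR adjusted p = 0.0193), a call that ended without wild type library 2 or mutant library 1 or 2 (0.0682 to 0.110). No member of the hedgehog list of 14 was called by edgeR, DESeq2 or voom, 0 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.880). The pathway genes sufu (-0.38, SE 0.18) and boc (-0.29, SE 0.17) were its most abundant members.

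Of 30 tested glycolysis genes, gpib alone was called, also when adjusted over the list alone (camera adjusted p = 0.857). gpib, for a glucose-6-phosphate isomerase, had 8.62 ± 4.22 CPM in mutant and 291 ± 27.3 in wild type (log2 fold change -5.07, SE 0.38, edgeR adjusted p = 0.000371). Its model in the table is long, from 512830 to 1011132 on chromosome 18. In the lipid handling list, 2 of 37 members fell and none rose, over all genes and when adjusted over the list alone (camera adjusted p = 0.910). The lipid droplet coat gene plin2 fell by 1.96 (SE 0.28, edgeR adjusted p = 0.00302) and hmgcs1, for a synthase of the cholesterol pathway, fell by 1.07 (SE 0.26, adjusted p = 0.0489). In the list for cholesterol and fatty acid synthesis, 1 of 17 members rose and 1 fell, over all genes and when adjusted over the list alone (camera adjusted p = 0.880), namely the lipogenic regulator srebf1 (0.94, SE 0.22, edgeR adjusted p = 0.0424) and hmgcs1. hmgcs1 (0.112 to 0.215) and srebf1 (0.0882 to 0.216) lost their calls when wild type library 2 or any 1 mutant library was left out. The adipocyte list had 1 lower member of 13, also when adjusted over the list alone (camera adjusted p = 0.796): the adiponectin gene adipoqa fell by 0.80 (SE 0.19, edgeR adjusted p = 0.0441), and kept its call only without wild type library 3 (otherwise 0.0624 to 0.195). Its model (chromosome 24, 26131764 to 26133811) overlaps that of and1 on the opposite strand, so the value of adipoqa is uncertain.

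In the heat shock and immediate early list, 4 of 36 members were lower, or 7 when adjusted over the list alone, and none was higher (median -0.54, camera adjusted p = 0.000827; adjusted p = 0.332 with an estimated correlation). hsp90aa1.1 stood at 417 ± 5.09 CPM in mutant and 1076 ± 376 in wild type (-1.37, SE 0.22, edgeR adjusted p = 0.00672). Its near-identical copy hsp90aa1.2 (-1.37, SE 0.23, adjusted p = 0.00882) has a model that overlaps it and is uncertain for that reason, while hspa4a (-0.76, SE 0.17, adjusted p = 0.0292) and hspb1 (-0.99, SE 0.24, adjusted p = 0.0479) are not near-copies of it. Both hsp90aa1 genes start within 10 Mb of runx2b on chromosome 20. For them a haplotype linked to the mutation and an effect of the genotype cannot be told apart. In the list for endoplasmic reticulum stress, 1 of 36 members was lower, or 8 when adjusted over the list alone (median -0.52, camera adjusted p = 0.000404; adjusted p = 0.332 with an estimated correlation). That member, the chaperone gene hspa5, fell by 1.52 (SE 0.31, edgeR adjusted p = 0.0338). Each of these 5 calls ended when any 1 mutant library was left out (adjusted p of 0.0517 to 0.213); those of hspa4a, hspb1 and hspa5 also ended without wild type library 2, and those of hspb1 and hspa5 without wild type library 1. Without wild type library 3 the counts were 7 lower and 1 higher in the heat shock list, and 12 lower and 2 higher in the endoplasmic reticulum stress list. Of 37 clock genes, 3 rose and 0 fell, or 3 and 2 when adjusted over the list alone (camera adjusted p = 0.0726, which was 0.000408 without wild type library 3, 0.0371 without mutant library 2, 0.0429 with library size only, 0.0404 with limma voom and 0.0492 with a replicate block). In these 5 settings the list was not called with an estimated correlation (adjusted p of 0.677 to 0.942), and 9 members rose without wild type library 3. The called genes were the core repressors per1a (2.56, SE 0.49, edgeR adjusted p = 0.0238) and cry1ab (1.00, SE 0.25, adjusted p = 0.0454) and the output regulator dbpa (0.96, SE 0.18, adjusted p = 0.0141). All 3 lost their calls when wild type library 2 or any 1 mutant library was left out (0.0517 to 0.201), and cry1ab also without wild type library 1.

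In the red blood cell list, 8 of 18 tested members rose and none fell, or 13 when adjusted over the list alone (median 0.74, camera adjusted p = 1.47e-10; adjusted p = 0.0287 with an estimated correlation). The number of higher members was 3 without wild type library 2, 1 without mutant library 1, 2 without mutant library 2 and 2 without mutant library 3. slc4a1a rose by 1.85 (SE 0.18, edgeR adjusted p = 0.000144), and the membrane skeleton genes sptb (1.00, SE 0.17, adjusted p = 0.00834) and epb41b (0.88, SE 0.18, adjusted p = 0.0186) and the heme synthesis gene alas2 (0.99, SE 0.19, adjusted p = 0.0167) rose with it. sptb lost its call without wild type library 2 or mutant library 1 (0.0570 to 0.0608), and epb41b and alas2 when any 1 mutant library was left out (0.0608 to 0.111). The summed globins hbaa1 and hbba1 had 1046, 1193 and 1028 CPM in wild type and 1250, 1293 and 1480 CPM in mutant. With an estimated correlation the list was not called once any single library was left out (adjusted p of 0.0788 to 0.158), nor with library size only (0.572), limma voom (0.0677) or the replicate block (0.302). In the endothelium list, 2 of 31 members rose and none fell, or 5 when adjusted over the list alone (median 0.29, camera adjusted p = 0.000971; adjusted p = 0.332 with an estimated correlation). They were lyve1a, a lymphatic marker (1.90, SE 0.29, edgeR adjusted p = 0.00526), and cdh5, for VE-cadherin (0.71, SE 0.16, adjusted p = 0.0337), which lost its call when wild type library 2 or any 1 mutant library was left out (0.0643 to 0.171). Without wild type library 3 the number of higher members was 5.

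In the neutrophil list, 3 of 12 tested members were lower, or 5 when adjusted over the list alone, and none was higher (median -0.59, camera adjusted p = 6.34e-05; and 0.217 with at least 50 counts in 3 libraries; adjusted p = 0.373 with an estimated correlation). The lysozyme gene lyz was 39.1 times lower by its counts (85 and 2; 95% counting interval 10.5 to 328; edgeR adjusted p = 0.003). cfl1l (-1.67, SE 0.30, adjusted p = 0.0105) and lect2l (-3.12, SE 0.67, adjusted p = 0.0335) fell too, and both lost their calls when any 1 mutant library was left out (0.0562 to 0.169), lect2l also without wild type library 2. In the macrophage list, 2 of 29 members were lower, or 6 when adjusted over the list alone (median -0.28, camera adjusted p = 0.000827, and 0.0568 without wild type library 2; adjusted p = 0.771 with an estimated correlation). The complement gene c1qb (-0.88, SE 0.21, edgeR adjusted p = 0.0398) and the cathepsin S gene ctss2.1 (-1.43, SE 0.35, adjusted p = 0.0449), whose model lies within that of its paralog ctss2.2 (-0.10), fell, and both lost their calls when wild type library 2 or any 1 mutant library was left out (0.0784 to 0.193). Without wild type library 1 the macrophage list had 7 lower members. Of 9 lymphocyte genes, edgeR, DESeq2 and voom called 0, 4 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.0698). The camera adjusted p was 0.00976 without wild type library 2 and 0.0479 without mutant library 3, against 0.361 and 0.867 with an estimated correlation. ikzf1 stood at 0.26 (SE 0.25) and tox at 0.07 (SE 0.24). Of 15 interferon genes, edgeR, DESeq2 and voom called 0, 2 had an unadjusted p under 0.05 and 1 was lower when adjusted over the list alone (camera adjusted p = 0.852). stat1a stood at 0.05 (SE 0.18) and irf9 at -0.20 (SE 0.16).

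Of 22 tested epidermis and scale genes, 2 fell and none rose, or 3 lower when adjusted over the list alone (camera adjusted p = 0.857). The epithelial adhesion gene epcam fell by 2.67 (SE 0.27, edgeR adjusted p = 0.000164) and the actinodin gene and1, of the fin fold fibrils, by 1.19 (SE 0.21, adjusted p = 0.0108). Without wild type library 1 the list was lower (camera adjusted p = 0.000102, with 4 called), but not with an estimated correlation (camera adjusted p = 0.631). Its camera direction was also down without wild type libraries 1 and 2, which leaves a lone wild type library. The call of and1 ended when wild type library 2 or any 1 mutant library was left out (edgeR adjusted p of 0.0615 to 0.0790). The model of and1 (chromosome 24, 26133004 to 26138318) overlaps that of adipoqa by 808 positions on the opposite strand, so its reads may not be separable from those of adipoqa. The pigment cell list had 1 lower member of 15, or 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.779): mycla fell by 1.73 (SE 0.42, edgeR adjusted p = 0.0435), and kept its call only without wild type library 3 (otherwise 0.0960 to 0.193). Of 24 nerve and Schwann cell genes, edgeR, DESeq2 and voom called 0, 7 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.857). The myelin genes mbpa and mbpb stood at -0.23 (SE 0.15) and -0.11 (SE 0.18). Across the lists, the median and the camera direction were positive and the mean negative for collagen, glycolysis, Wnt and chondrocyte genes. For epidermis and hedgehog genes the median was positive, and the mean and the camera direction were negative.

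In the yolk and egg coat list, 4 of 7 tested members fell, also when adjusted over the list alone, and none rose (camera adjusted p = 5.52e-36; adjusted p = 0.0252 with an estimated correlation). With an estimated correlation that call was lost when any 1 library was left out (adjusted p of 0.0591 to 0.158), with the replicate block (0.302) and with limma voom (0.365). Without wild type library 3 the list had 11 lower members. vtg1 had 680 counts in wild type and 4 in mutant, vtg4 666 and 4, vtg7 395 and 4, and vtg5 110 and 3. The log2 fold changes were -7.15 (SE 0.42), -7.13 (SE 0.41) and -6.39 (SE 0.41) for the first 3 of these, with edgeR adjusted p-values of at most 0.000849 for all 4. For vtg5 the count ratio of wild type to mutant was 33.8 (95% counting interval 11.3 to 166). Their models overlap on chromosome 22 between 24703341 and 24830426, so the split of reads between them is uncertain. Summed vitellogenin stood at 31.6, 31.5 and 33.1 CPM in the wild type libraries and 0.233, 0.604 and 0.382 CPM in the mutant libraries. Egg coat (zona pellucida) transcripts summed to 27.7, 13.5 and 0.913 CPM in wild type libraries 1 to 3 and to 0.653, 1.87 and 0.491 CPM in the mutant libraries. Leaving out wild type libraries 1 and 2 leaves a lone wild type library, so calls in that setting do not measure the spread within wild type. The library that is kept had 33.1 CPM of vitellogenin, so that setting would not remove a difference in sex between the groups. Without wild type libraries 1 and 2, edgeR called 427 genes, of which 32.1% were higher in the mutant against 52.1% among the 476, and 177 were shared. Of the 62 called genes named here, 32 lost their call in that setting.

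**Figure D2:**
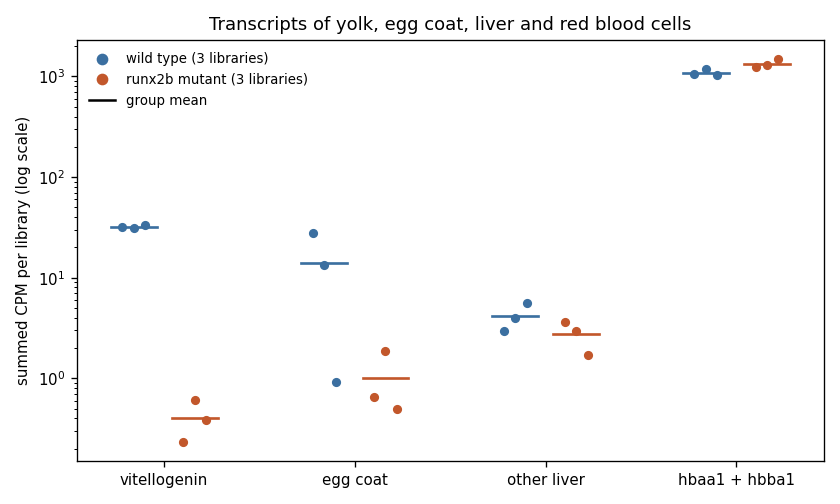
Summed CPM per library, on a log axis, of 7 vitellogenin genes, 11 egg coat genes, 12 other liver transcripts and the globins hbaa1 and hbba1, with a line at each group mean. Vitellogenin lies between 31.5 and 33.1 CPM in every wild type library and at or under 0.604 CPM in every mutant library, while egg coat transcripts are high in wild type libraries 1 and 2 only.

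Of 30 cell cycle genes, edgeR called 0, with 1 higher and 8 lower at an unadjusted p under 0.05, 2 lower by DESeq2, 0 by voom and 0 when adjusted over the list alone. The list was lower by camera (median -0.62, adjusted p = 0.00398; adjusted p = 0.902 with an estimated correlation), but not without wild type library 1 (adjusted p = 0.479), and without wild type libraries 1 and 2 its direction was upward (adjusted p = 0.704); without wild type library 3, 7 members were lower and 1 higher. hmgb2a stood at -0.16 (SE 0.16) and mcm6 at 0.14 (SE 0.15). Of the 13 mitochondrially encoded genes, edgeR called 0, with 6 lower at an unadjusted p under 0.05, 3 lower by DESeq2, 0 by voom and 4 lower when adjusted over the list alone. The list was lower by camera (median -0.30, adjusted p = 0.00931; adjusted p = 0.769 with an estimated correlation), but not without wild type library 1 (0.0588) or mutant library 3 (0.0662), and without wild type library 3 edgeR called 3 members lower. These transcripts took 7.34%, 5.56% and 4.59% of counts in the wild type libraries and 4.73%, 4.44% and 3.60% in the mutant libraries. mt-atp6 stood at -0.76 (SE 0.22, edgeR adjusted p = 0.0820) and mt-co1 at 0.15 (SE 0.19).

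**Figure D3:**
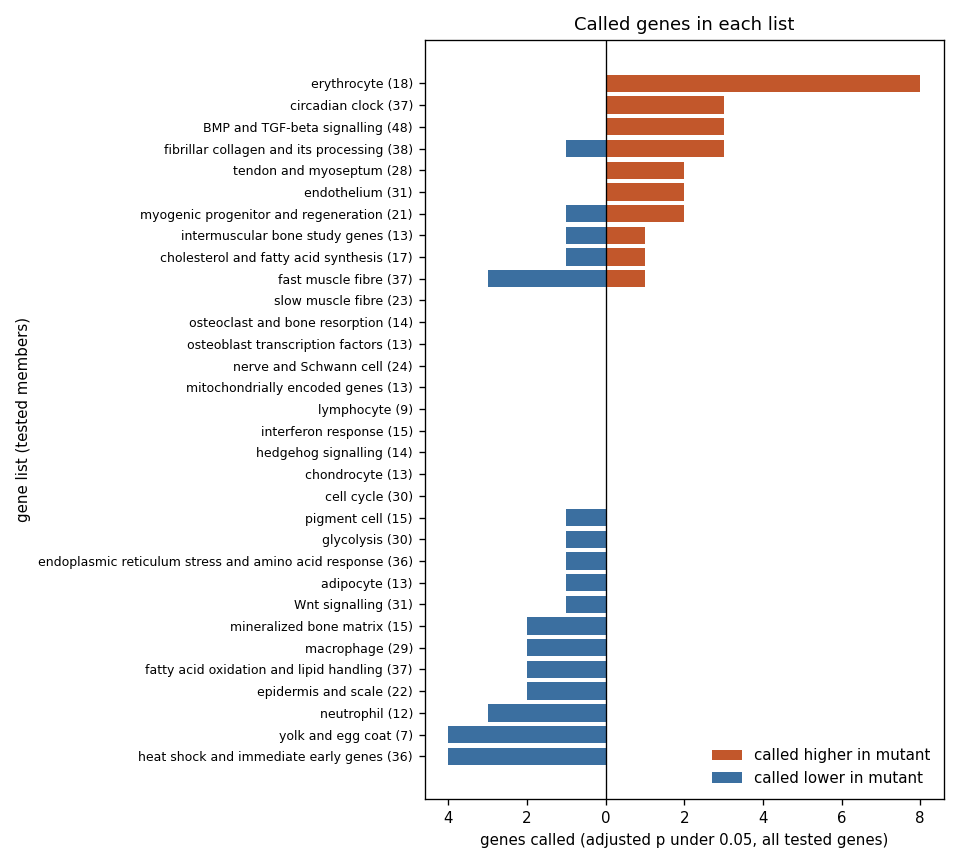
Number of genes called higher (right) and lower (left) in the mutant in each of 32 lists, with the number of tested members in brackets. The red blood cell list has 8 higher members of 18, and the yolk list and the heat shock list have 4 lower members each.

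Among single genes outside these lists, tulp1a (chromosome 23, 5529820 to 5562431), of a family studied in photoreceptors, had 77 counts in mutant and 1 in wild type, a ratio of 83.7 (95% counting interval 14.6 to 3347). The integrin gene itgam of myeloid cells (3.72, SE 0.62, edgeR adjusted p = 0.009), znf1106 (2.91, SE 0.47, adjusted p = 0.00672), the anion transporter gene slc26a6 (2.57, SE 0.57, adjusted p = 0.0288) and the cathepsin B gene ctsba (2.03, SE 0.18, adjusted p = 5.69e-05) also rose. itgam is in neither the neutrophil nor the macrophage list, and its rise runs against the falls in those lists. The model of znf1106 lies within the wide models of 2 called clone-named genes and is uncertain. lcp2b (1.99), cgref1 (1.98) and gig2e (1.94) completed the largest rises with per1a and lyve1a. The models of ctsba (32670420 to 32679003) and cgref1 (32678278 to 32684022) overlap on opposite strands of chromosome 17, so their reads may not be separable. Among the falls, prok1, for a prokineticin, had 90 counts in wild type and 0 in mutant (at least 27.6-fold lower; counting interval from 22.0), and btr07 had 85 and 0 (at least 26.1-fold lower; counting interval from 20.8). The laminin gene lama1 had 275 and 5 counts (-5.59, SE 0.82, edgeR adjusted p = 0.0135), and osbpl7 had 61 and 3, a ratio of 18.7 (95% counting interval 6.11 to 93.3). itgam, lcp2b, gig2e and slc26a6 lost their calls when wild type library 2 or any 1 mutant library was left out, and slc26a6 also without wild type library 1 (0.0563 to 0.188). cgref1 lost its call without wild type library 2 or mutant library 2 or 3 (up to 0.0844), lama1 when any 1 mutant library was left out (0.0928 to 0.117), osbpl7 without mutant library 2 or 3 (0.0562 to 0.0666) and znf1106 without mutant library 1 (0.0608).

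Haplotypes linked to a selected mutation can differ between mutant and wild type fish, so calls near runx2b were counted. On chromosome 20, 16 of 553 tested genes were called (odds ratio 0.845, 95% interval 0.475 to 1.40, Fisher's exact p = 0.631). That odds ratio was 0.365 without mutant library 1 and 1.09 without mutant library 3. Within 10 Mb of runx2b, 9 of 189 tested genes were called (odds ratio 1.43, 0.642 to 2.81, Fisher's exact p = 0.305). Among the 9 are hsp90aa1.1 (start 54192871) and hsp90aa1.2 (start 54177625), whose models overlap and may not be separate calls. Chromosome 20 held 3.36% of all calls (95% interval 1.93 to 5.40).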

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

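The length correction, the removal of mitochondrially encoded and abundant genes, and the removal of both wild type libraries with egg coat transcripts were chosen only after the results were seen. The remaining settings were planned. Every called gene shared between a setting and the 476 kept its direction, in all 19 alternative settings. For the fold threshold and the stricter adjusted p this was fixed in advance, since they use the same fit. The other settings use the same or most of the same libraries, and shared genes are called in both fits. A kept direction is therefore weak evidence. The cause of the changes below was not tested, except that a stricter threshold lowers a count by construction.

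The number of called genes was 474 with RLE scaling (472 shared with the 476), 445 with upper-quartile scaling, 361 with library size only (47.4% higher in the mutant), 348 by limma voom, 377 with a replicate block (314 shared), 420 with a length correction (385 shared) and 466 without mitochondrially encoded genes and the 20 most abundant genes. It was 654 by DESeq2 (430 shared). Without a low-count filter the count was 1161 (549 higher, 612 lower), and with at least 50 counts in 3 libraries 304 (177 higher, 127 lower). It was 311 at an absolute log2 fold change of at least 1 (141 higher) and 123 at an adjusted p under 0.01 (50 higher, 73 lower). Without wild type libraries 1 and 2, which leaves a lone wild type library that is assumed to vary like the mutant libraries, 137 of 427 called genes were higher. Deviations from the group means of same-numbered libraries correlated at -0.0553, 0.0348 and 0.0306 across genes, and those of unlike-numbered libraries at -0.13 to 0.107. The labels do not say whether equal numbers share a batch, and these few values cannot exclude it.

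Without 1 library at a time the number of called genes ran from 115 to 1225 (50 to 572 higher, 65 to 653 lower). The odds ratio of chromosome 20 ran from 0.365 to 1.09. It was 1.00 with at least 50 counts, 1.04 with DESeq2 and 1.26 at an adjusted p under 0.01. The difference in runx2b CPM, which is 0.0363 with all libraries, was -0.129 without wild type libraries 1 and 2. Of 32 lists, 10 were called by camera, 2 with an estimated correlation and 2 by fry in 1 direction.

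Uncalled genes whose log2 fold change changed sign without 1 library had these ranges: bmp6 -0.56 to 0.21, col1a1a -0.0028 to 0.45, scxa -0.22 to 0.12, spp1 -1.58 to 0.18, tnmd -0.0386 to 0.38, mef2cb -0.0893 to 0.0890, col2a1b -0.0931 to 0.29, mmp14a -0.0881 to 0.0639, tnnt2e -0.19 to 0.14, stat1a -0.11 to 0.22, tox -0.0584 to 0.24, mbpb -0.22 to 0.0236 and mt-co1 -0.0408 to 0.33. Without wild type libraries 1 and 2 the values with a changed sign were col1a1a -0.0213, col1a2 -0.0097, scxa 0.44, col11a1b -0.0867, col2a1b -0.21, tnnt2e 0.27, hmgb2a 0.0253, mcm6 -0.0023 and stat1a -0.26. With the length correction they were scxa 0.0589, col11a1b -0.0256, col2a1b -0.0339, smyhc2 -0.0605, tnnt2e 0.0108 and stat1a -0.0061.

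The camera direction of some lists without a call changed, with these adjusted p-values. Without 1 library at a time they ran over 0.543 to 0.939 (chondrocyte), 0.599 to 0.969 (Wnt), 0.669 to 0.992 (hedgehog), 0.360 to 0.879 (fast muscle), 0.302 to 0.969 (myogenic), 0.402 to 0.939 (glycolysis), 0.474 to 0.937 (lipid handling), 0.687 to 0.939 (cholesterol), 0.344 to 0.879 (interferon), 0.404 to 0.993 (nerve) and 0.000102 to 0.939 (epidermis). Without a filter they were 0.864 (osteoclast), 0.841 (hedgehog), 0.841 (cholesterol), 0.826 (interferon) and 0.814 (nerve). With at least 50 counts they were 0.898 (osteoblast transcription factors), 0.974 (collagen), 0.912 (chondrocyte), 0.898 (osteoclast), 0.855 (myogenic), 0.898 (cholesterol) and 0.855 (pigment). The chondrocyte list had 0.854 with library size only, 0.860 with the block and 0.769 with the length correction, the lipid handling list 0.909 with voom and 0.874 with the block, and the epidermis list 0.724 with voom. Without wild type libraries 1 and 2 the values were 0.540 (osteoblast transcription factors), 0.897 (hedgehog), 0.144 (myogenic), 0.704 (cell cycle, called with all libraries), 0.933 (glycolysis), 0.196 (circadian), 0.878 (interferon) and 0.906 (adipocyte).

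Of the 62 called genes named in the report, 18 kept their call without each single library, and the call was lost by 11 genes without wild type library 1, 32 without wild type library 2, 1 without wild type library 3, 38 without mutant library 1, 38 without mutant library 2 and 39 without mutant library 3. All 62 kept their direction in these fits, which share most libraries with the main fit. Log2 fold changes moved little for some genes (bmpr2b, 0.838 to 0.889) and more for others (itgam, 3.08 to 5.14). In other settings the same 62 genes lost calls as follows, with the range of adjusted p-values: DESeq2 4 (bmpr2b, cry1ab, p3h2, plod2; 0.0578 to 0.110), RLE 1 (p3h2, 0.0505), upper-quartile 6 (bmpr2b, hmgcs1, hspb1, myhz1.2, p3h2, plod2; 0.0502 to 0.0559), no filter 1 (bglapl, 0.0503), at least 50 counts 6 (adipoqa, hmgcs1, hspb1, myhz1.2, plod2, srebf1; 0.0526 to 0.0644) and without mitochondrially encoded and abundant genes 2 (myhz1.2, p3h2; 0.0529 to 0.0532). Library size only ended 16 (adipoqa, alas2, bmpr2b, c1qb, cdh5, cry1ab, ctss2.1, dbpa, hmgcs1, hspa4a, hspb1, myh9a, p3h2, plod2, srebf1, tgfb2; 0.0526 to 0.156). limma voom ended 16 (adipoqa, bmpr2b, c1qb, cry1ab, ctss2.1, hmgcs1, hspb1, lama1, lect2l, mycla, myh9a, p3h2, plod2, slc26a6, srebf1, tgfb2; 0.0549 to 0.116). The replicate block ended 17 (adipoqa, bglapl, bmpr2b, c1qb, cgref1, cry1ab, ctss2.1, frzb, gig2e, hmgcs1, hspa4a, hspa5, myh9a, p3h2, plod2, srebf1, tgfb2; 0.0504 to 0.0841). The length correction ended 11 (adipoqa, bmpr2b, c1qb, cdh5, cry1ab, ctss2.1, hspb1, p3h2, plod2, srebf1, xirp2a; up to 0.0897). Leaving out wild type libraries 1 and 2 ended 32, lyve1a (0.0537) and lyz (0.0751) among them, with values up to 0.549. Among lists, the mitochondrially encoded list was not called with the length correction (0.0511) or without wild type libraries 1 and 2 (0.1003), the cell cycle list not with at least 50 counts (0.383), and the lymphocyte list was called with the length correction (0.0415; adjusted p = 0.567 with an estimated correlation). With at least 50 counts and an estimated correlation the red blood cell list had 0.0912, and without wild type libraries 1 and 2 the red blood cell and yolk lists had 0.308 each. Counts were low for the bone transcription factors runx2b, runx2a and sp7, with at most 12 per group, where 3 counts correspond to 0.134 to 0.181 CPM. Whether depth or low expression lay behind this was not tested.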

Other observations

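Called genes were spread unevenly over the chromosomes. Chromosome 4 held 45 called of 627 tested genes (odds ratio 2.33, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 5.35e-05) and chromosome 24 held 28 of 410 (odds ratio 2.16, adjusted p = 0.00529). Chromosome 6 held 9 of 613 (odds ratio 0.414, adjusted p = 0.0349). Fisher's exact test takes genes as independent, which neighbouring or overlapping models are not, so these p-values may be too small. On chromosome 4 the called genes include such neighbours, si:dkey-238k10.1 and si:dkey-238k10.2 among them. The test was not repeated per chromosome after thinning such models. Of 56 pairs of consecutive called genes with starts within 100 kb, 43 changed in the same direction and 13 in opposite directions. The pairs include overlapping models and near-identical paralogs, such as those of vitellogenin and hsp90aa1, whose reads may not be separable. No chance value was computed for this tally, so it does not measure co-regulation. Among these pairs, picked after their values were seen, tulp1a (5.92) lies beside tead3a (1.62) on chromosome 23. On chromosome 14, lcp2b (1.99) lies between tmsb2 (-2.30) and SYCE3 (-2.13).

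For the patterns below, the length correction and the tests of liver transcripts, egg coat transcripts, globins and neighbouring genes, including chromosome 20, were chosen only after the results were seen; the splits of the libraries were planned. The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 476 genes, a number reached by 1 of the 10 splits, the real one itself, and the highest other split called 2. For the lists, 4 of the 10 splits called as many as the real split, which called 10, and the highest other split called 14.

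Vitellogenin was lower in every mutant library, with a log2 difference of -6.41 (SE 0.398) in the summed CPM of 7 genes. Vitellogenins are made in the liver of egg-laying females, so more liver RNA in the wild type libraries was tested first: 12 other liver transcripts differed by -0.618 (SE 0.424), far less than vitellogenin, which argues against it. Wild type fish may have included egg-bearing females where mutant fish did not. Egg coat transcripts lay over 5 times above the highest mutant library in 2 of the 3 wild type libraries, and the third had vitellogenin without them, so this explanation and an effect of the genotype cannot be told apart. Sex is not given in the sources used here. A difference in sex between the groups could bear on all 476 calls, not on vitellogenin alone.

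Red blood cell genes were higher in the mutant, with a median log2 fold change of 0.994 over the 8 called members. More red blood cells in the mutant samples would raise all globins, but the most abundant, hbaa1 and hbba1, together differed by only 0.299 (SE 0.101), which argues against a larger share of such cells as the whole cause, although the minor globin hbaa2 (7.30 CPM in mutant), itself among the 8, rose by 1.08 (SE 0.256). Gene length bias was also argued against, since 7 of the 8 members stayed called after length correction and the mean log2 fold change of all 8 was 96.3% of its value; fech, named after its values were seen, went from 1.36 (SE 0.341, edgeR adjusted p = 0.0499) to 1.24 (SE 0.345, adjusted p = 0.0789). An effect of the genotype stays open and was not tested. Which cells of the tail muscle held the transcripts of this list was not tested either.

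Called genes lay near each other on the chromosomes: 100 of 463 had a called neighbour within 100 kb, where 49 were drawn at random (permutation p = 1e-05, the smallest that 100000 draws give). Reads shared between overlapping models or paralogs could add to this, since after thinning such models 49 of 401 had a called neighbour, 1.45 times the number drawn (permutation p = 0.0314) and no more than 49, the upper end of the central 95% of draws. A haplotype linked to the runx2b mutation is argued against as the whole cause, since chromosome 20 held 3.46% of these genes (upper 95% limit 5.55%). Unlinked haplotypes that differ between the fish remain open, as does co-regulation of neighbours: after thinning and without chromosome 4 the excess was 1.35 times (permutation p = 0.0915). These explanations cannot be told apart with the gene counts alone.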
